A study of Mus musculus with 11 samples.

How the data were processed

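Total RNA of mouse skin and skin tumors was depleted of ribosomal RNA and sequenced as single reads of 50 bp, per the labels' protocols, on a HiSeq3000 or a NovaSeq6000. The labels do not say which library ran on which instrument, and a sample sheet places 6 libraries in a first run (WT skin 1 to 3, Dlx3 KO skin 2 and 3, tumor 5) and 5 in a second. The sample sheet gives 29265111 to 75707445 alignments per library. Reads were prepared with bcl2fastq 2.20.0.422 and mapped to mm10 with TopHat2 2.1.1 and Bowtie, per the submitters' processing notes, which give no versions for Bowtie and Partek. The RPKM values were computed per gene with Partek by the authors, per the file headers, and are not log transformed. The authors' deposited ANOVA table holds group means on the log2 scale, which equal the means of log2(RPKM + 0.1) within 4.92e-05. The p-value and q-value of each gene come from the ANOVA of the authors in Partek, per the file headers, which do not state its terms. A one-way ANOVA with contrasts gave p-values within 0.001 of theirs for 99.9%, 95.0% and 94.9% of genes in the 3 comparisons. The ratio of each comparison in the authors' deposited table is 2 to the power of the difference of those means.

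Expression was analysed here from the RPKM table of 24974 genes, of which 1143 were at 0 in every library. Values were taken as log2(RPKM + 0.5), and the 14233 genes with a mean of at least 0.5 RPKM over the 11 libraries were tested. RPKM of a gene are shares of the library scaled to gene length, so a large change in abundant transcripts moves all others. The 10 genes highest in RPKM held 6.67% to 17.7% of the summed RPKM of a library, which is not a share of reads. Counts per gene are not used here, so precision at low values was judged from the spread between libraries. The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend and robust, 8 residual degrees of freedom before moderation). Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Of 40 gene lists fixed in advance, 39 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, adjusted over lists. Camera with a correlation estimated from the data and fry were run as alternatives. Camera with the preset correlation treats members of a list as nearly independent, so each list is given with its p under an estimated correlation.

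The groups, the comparisons, the gene lists, the alternative settings and the rule for named genes were chosen before the data were examined. The rule took, per comparison and direction, the 10 called genes with the largest log2 fold change and groups that did not overlap, without predicted, clone-named, small RNA, ribosomal RNA and immune receptor genes. With fewer than 5 such genes, it took the 5 with the largest moderated t, named as not passing. It added up to 4 members with the smallest p of each list described, genes called in both steps, and always Dlx3, Egfr, Erbb2 and Erbb3. Genes of sex chromosomes and Rn45s were given as properties of libraries and chosen for that after their values were seen. Simulated data of this design held 200 changed genes. Noise was drawn independently for each gene and library, with one spread per gene in all groups. At log2 changes of 1, 2 and 4, 16.4%, 80.6% and 90.9% were found in Dlx3 KO skin against WT skin, 22.4%, 86.6% and 97.0% in tumor against Dlx3 KO skin and 20.9%, 83.6% and 97.0% in tumor against WT skin. Genes called there without a simulated change were 9 of 134, 5 of 142 and 7 of 141. In a simulation for lists, camera found the shifted list and called 0 others. Its genes were drawn independently, so it does not test camera where members of a list vary together. In the data the shifted list, that of hair shaft genes, had an estimated correlation of 0.727.

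Alternatives covered the pseudocount, the filter, median-ratio and quantile scaling, limma settings, library weights, run as a term, the compared groups alone, a replicate block and leaving out each library. Those chosen after seeing the data were the Xist level as a term, libraries with high Xist alone, each run alone, leaving out the 2 libraries high in Rn45s, and the overlap at unadjusted p. Gene positions are from GENCODE M21 on GRCm38 (mm10), in which 24458 symbols (97.9%) were matched. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 drew the figures and tables. Raw reads, splicing and the deleted exon of Dlx3 were not analysed here. One gene that the rule for named genes selects is not reported here.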

Results

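Gene expression was measured by RNA sequencing in mouse skin and skin tumors after topical treatment with DMBA, a polycyclic hydrocarbon that mutates DNA and starts squamous tumors in mouse skin. Animals were wild type (WT) or carried a conditional knockout (KO) of Dlx3, a homeobox transcription factor of the upper epidermis and the hair follicle. All received 3 doses of 100 µg in 200 µl at intervals of 1 week, and tissue was collected at week 31. The 11 libraries were WT skin (n = 3), Dlx3 KO skin (n = 3), described as whole skin without lesions, and Dlx3 KO tumors (n = 5). The labels do not tie tumors or skins to animals, so tumors may share an animal with each other or with a Dlx3 KO skin, and p-values measure the spread between these samples. Each library had 29265111 to 75707445 alignments. No 2 libraries of a group held identical values, and the correlation between libraries of a group ran from 0.887 to 0.952 in WT skin, from 0.965 to 0.980 in Dlx3 KO skin and from 0.874 to 0.972 in tumors.

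The targeted gene was examined first in every library. Dlx3 (GENCODE M21 on mm10, chromosome 11, 95120119 to 95125296, plus strand, 1 transcript with 3 exons) was measured in RPKM, mapped reads scaled to gene length and library size. It was at 49.9, 7.35 and 89.9 RPKM in the libraries labelled WT skin 1, 2 and 3. It was at 4.08, 8.88 and 6.72 RPKM in the Dlx3 KO skins and at 4.16, 7.61, 7.52, 1.93 and 1.34 RPKM in the tumors. The library labelled WT skin 2 thus lay within the range of the Dlx3 KO skins. The deleted exon is not given in the sources used here, so a value over the whole gene is a limited check of the genotype. Dlx3 differed between Dlx3 KO skin and WT skin by a log2 fold change of -2.28 ± 0.83 (SE; limma adjusted p = 0.440), which became -3.32 (adjusted p = 0.0307) without the library labelled WT skin 2. Dlx3 was lower in tumors than in WT skin (log2 fold change -2.96 ± 0.74, SE, adjusted p = 0.0207). This call was lost with sequencing run as an added term and without WT skin 1 or WT skin 3 (adjusted p = 0.0967 without WT skin 3).

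**Figure D1:**
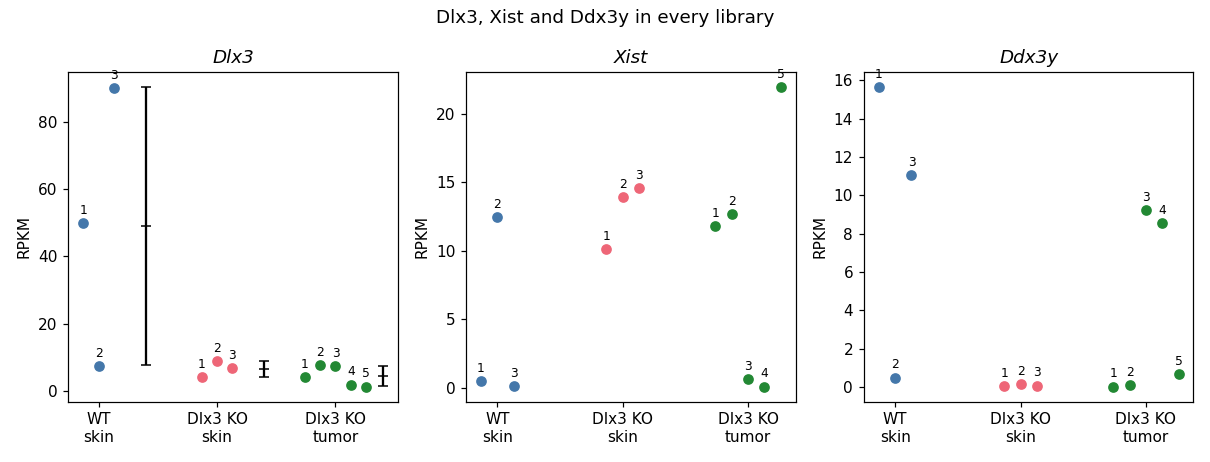
Each point is the RPKM of 1 library on a linear axis for Dlx3, Xist and Ddx3y, grouped as WT skin (n = 3), Dlx3 KO skin (n = 3) and Dlx3 KO tumor (n = 5), with replicate numbers beside the points and the mean ± SD drawn for Dlx3. The library labelled WT skin 2 has 7.35 RPKM of Dlx3, near the Dlx3 KO skins (4.08 to 8.88), and 12.5 RPKM of Xist, unlike WT skin 1 (0.466) and WT skin 3 (0.149).

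The labels give no sex. Xist, the RNA that coats the silenced X chromosome of females, was at 0.466 and 0.149 RPKM in WT skin 1 and 3 and at 0.616 and 0.0941 RPKM in tumors 3 and 4. The Y-linked gene Ddx3y was at 15.7, 11.1, 9.22 and 8.54 RPKM in those 4 libraries. The other 7 libraries, which include the library labelled WT skin 2 and all 3 Dlx3 KO skins, had 10.1 to 22.0 RPKM of Xist and at most 0.687 RPKM of Ddx3y. Among these 7, Ddx3y was highest in tumor 5 (0.687 RPKM) and the library labelled WT skin 2 (0.492 RPKM), against 0.0209 to 0.157 RPKM in the rest. Likewise the Y-linked gene Eif2s3y was at 1.55 and 1.26 RPKM in these libraries, against 0.0906 to 0.302 RPKM in the rest. The source of these Y-linked reads was not tested. Rn45s, the precursor of ribosomal RNA, reached 10021 RPKM in WT skin 1 and 11833 RPKM in tumor 5, against 612 to 3242 RPKM in the other libraries. The first principal component, with 49.6% of the variance, set tumors 2 to 5 (65.3 to 76.7) apart from the skins (-84.4 to -26.1), and tumor 1 lay between them at 18.4. The library labelled WT skin 2 (-55.1) lay there beside WT skin 1 (-53.0) and outside the Dlx3 KO skins (-47.0 to -26.1). On the second component, with 22.1% of the variance, the library labelled WT skin 2 (-13.1) lay nearer to the Dlx3 KO skins (-41.0 to -27.3) than to WT skin 1 (67.0) and WT skin 3 (41.8). Tumor 5 (60.5) lay there near WT skin 1, and the other tumors lay at -49.8 to 10.4. The second component therefore does not follow genotype alone.

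**Figure D2:**
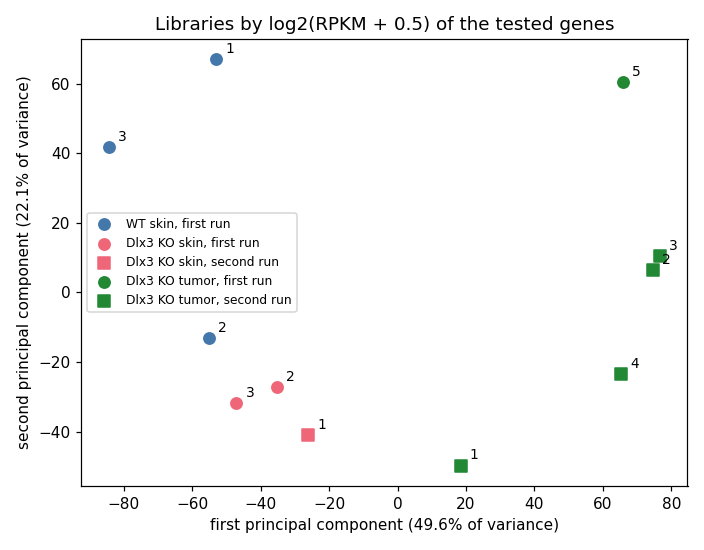
Principal components of log2(RPKM + 0.5) over the 14233 tested genes, with the first component (49.6% of the variance) on the horizontal and the second (22.1%) on the vertical axis. Each point is 1 library with its replicate number, colors are the 3 groups, and circles and squares are the 2 sequencing runs; tumor 1 lies at 18.4 on the first component and the other tumors at 65.3 to 76.7.

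What loss of Dlx3 does in treated skin without a tumor was addressed by comparing Dlx3 KO skin with WT skin (n = 3 each). Structural genes of the hair were on average far lower in Dlx3 KO skin than in WT skin. Genes of stressed, hyperproliferative epidermis were higher, although no single gene passed adjustment over all genes. The fall of hair genes rested mainly on WT skin 1 and 3. The library labelled WT skin 2 lay near the Dlx3 KO skins (hair shaft median 10.6 RPKM against 1.57 to 9.97 RPKM). The cause of this fall was not tested. The list of hair shaft and inner root sheath genes lay lower in 58 of its 59 tested members (median log2 fold change -3.62, camera adjusted p = 3.06e-51). With an estimated correlation, adjusted p = 0.573 for this list. Keratin-associated proteins fill the hair cortex. Among them, Krtap16-3 was at 0.551 ± 0.450 RPKM in Dlx3 KO skin and 134 ± 123 RPKM in WT skin (SD, n = 3 each, log2 fold change -5.88, limma adjusted p = 0.256). Krtap6-1 and Krtap6-2 had log2 fold changes of -5.73 and -5.69, and the hair keratin Krt34 had -4.06. Adjusted over the list alone, 50 of the 59 members were lower and 0 higher. The hyperproliferative and stress epidermis list was higher in 38 of 41 tested members (median log2 fold change 2.61, camera adjusted p = 1.54e-15; adjusted p = 0.573 with an estimated correlation). Of these, 19 were higher and 0 lower when adjusted over the list alone. Its members with the smallest p were small proline-rich proteins of the cornified envelope. Sprr2e was at 32.2 ± 8.38 RPKM in Dlx3 KO skin and 1.54 ± 1.47 RPKM in WT skin (SD, n = 3 each, log2 fold change 4.31, limma adjusted p = 0.256). Sprr2g, Sprr2i and Sprr2f had log2 fold changes of 3.98, 3.73 and 3.09. Members of the Sprr2 and Krtap families resemble each other closely, so reads shared between copies leave single members uncertain.

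Terminal differentiation, inflammation and cell division lists also differed between Dlx3 KO skin and WT skin. The cornified envelope list was higher in 42 of 44 members (median log2 fold change 1.54, camera adjusted p = 4.55e-10; adjusted p = 0.573 with an estimated correlation). Members with small p were the lipoxygenase Alox12b (74.3 ± 9.18 against 19.2 ± 17.4 RPKM, SD, n = 3 each), the protease inhibitor Spink5 (130 ± 19.9 against 62.6 ± 8.74 RPKM) and the protease Klk8 (213 ± 25.9 against 95.7 ± 102 RPKM). In the library labelled WT skin 2, Klk8 was at 213 RPKM, within the range of the Dlx3 KO skins (184 to 234 RPKM). Alox12b (39.2 RPKM, Dlx3 KO skins 63.7 to 80.4 RPKM) and Spink5 (67.8 RPKM, Dlx3 KO skins 113 to 152 RPKM) lay below them in that library. Adjusted over the list alone, 0 members passed. Genes of the IL-17 axis, which draw neutrophils to skin, were higher in 18 of 20 members (median log2 fold change 0.74, camera adjusted p = 0.000618; adjusted p = 0.573 with an estimated correlation). When adjusted over the list alone, 1 member was higher. Examples were Il1a (log2 fold change 1.72), the iron-binding Lcn2 (2.45) and the chemokine Ccl20 (1.67). All 37 members of the G2 and M phase list were lower (median log2 fold change -0.45, camera adjusted p = 5.24e-10; adjusted p = 0.573 with an estimated correlation). They include Pbk (-0.90) and Cdc25c (-0.92), and 0 passed when adjusted over the list alone. The ERBB list, the receptor family in the title of the series and its ligands, did not pass (10 of 13 members higher, median log2 fold change 0.23, camera adjusted p = 0.0945, and 0.0452 in the first run alone), with 1 member higher when adjusted over the list alone. Egfr (6.39 ± 0.936 against 5.65 ± 2.52 RPKM, SD, n = 3 each, limma adjusted p = 0.880) did not pass. Neither did Erbb2 (25.7 ± 2.36 against 20.5 ± 8.72 RPKM, adjusted p = 0.835) and Erbb3 (16.2 ± 3.40 against 11.6 ± 5.20 RPKM, adjusted p = 0.744). The EGFR ligand epiregulin, Ereg, had a log2 fold change of 1.85 (9.70 ± 4.81 against 2.15 ± 0.350 RPKM, adjusted p = 0.256).

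Among single genes, 0 of 14233 passed an adjusted p of 0.05 in limma between Dlx3 KO skin and WT skin, 1229 had an unadjusted p under 0.05 against 712 by chance. Of all genes, 16.4% had groups that did not overlap, against 10% by chance. In simulated data of this design, 80.6% of genes changed by 2 on the log2 scale were found. That simulation gave each gene one spread in all groups and does not hold for genes that vary widely between the WT skins. The hair shaft list had 0 of 59 members called at a median log2 fold change of -3.62. The absence of called genes thus does not mean that large changes are absent. Among all tested genes none passed. The largest positive moderated t belonged to Fgfbp1, a secreted carrier of fibroblast growth factors (122 ± 15.0 against 29.6 ± 11.4 RPKM, SD, n = 3 each, limma adjusted p = 0.0742). Next came the retinol-binding Rbp2 (log2 fold change 2.28), Tmigd1 (2.48), the ceramide enzyme Degs1 (1.64) and Duoxa1 (1.62), a maturation factor of a hydrogen peroxide-forming oxidase. The last 4 had adjusted p = 0.201. In the other direction were Apoc4 (-1.44) and Dupd1 (-2.30), with adjusted p = 0.201, and the fatty acid receptor Ffar2 (-1.65), Krtap4-8 (-4.27) and Krtap16-3, with adjusted p = 0.256. The WT mean of this comparison includes the library labelled WT skin 2, which had 10.6 RPKM as the median of the hair shaft list. The median was 170 and 250 RPKM in WT skin 1 and 3 and 1.57 to 9.97 RPKM in the Dlx3 KO skins. Without it, 229 genes changed, 63 risen and 166 fallen, with 45 hair shaft members fallen (median log2 fold change -4.92) and 7 hyperproliferative members risen and 1 fallen (median 3.43). In that fit both WT skins have low Xist and all Dlx3 KO skins high Xist, so sex and genotype cannot be separated. Weighting libraries gave 2 genes. Fits with another scaling, filter or pseudocount or with run as an added term gave 0. The first run alone gave 0, with medians of -3.14 for the hair shaft list and 2.83 for the hyperproliferative list (the second run holds 1 Dlx3 KO skin and no WT skin). Among the 4 skins with high Xist, where the only WT library is the one labelled WT skin 2, the list medians were -1.19 for hair shaft, 0.93 for hyperproliferative and 0.29 for cornified envelope genes. That single WT library is taken to vary like the others and its genotype label is in doubt, so these medians do not test the difference between genotypes. With the Xist level as an added term, the IL-17 list no longer passed (camera adjusted p = 0.0658).

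The tumors were compared with Dlx3 KO skin to ask what separates a tumor (n = 5) from skin of the same genotype without lesions (n = 3). Most skeletal muscle (19 of 20), adipocyte (14 of 15) and nerve genes (6 of 9) fell in tumors. Single genes of other kinds rose, among them the keratins Krt13 and Krt6a, the detoxifying enzymes Gsta4 and Gsta1 and the cell division gene Cdc20. Krt13, a keratin of non-cornified mucosal epithelium, rose from 1.82 ± 0.346 RPKM (SD, n = 3) to 380 ± 562 RPKM (n = 5; log2 fold change 6.27 ± 0.88, SE, limma adjusted p = 0.00126). Single tumors had 47.9 to 1374 RPKM. Gsta4, a glutathione transferase that removes products of lipid peroxidation, rose from 14.8 ± 7.95 to 1056 ± 637 RPKM (log2 fold change 6.08, adjusted p = 0.000129). The protease inhibitor Slpi (log2 fold change 5.24), arginase Arg1 (5.19), the envelope proteins Sprr3 (4.85) and Sprr2k (4.85), the sphingolipid enzyme subunit Sptssb (3.94), the adaptor Sh2d5 (3.90), the homeobox factor Pitx1 (3.88) and the membrane protease Tmprss11b (3.67) also rose. Of these, the calls of Sptssb, Sprr3 and Sh2d5 depended on single libraries and were kept in 2, 5 and 7 of the 8 fits that each left out 1 library.

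Skeletal muscle genes fell most of all named genes. Actin Acta1 fell from 2419 ± 1157 RPKM in Dlx3 KO skin (SD, n = 3) to 33.2 ± 40.9 RPKM in tumors (n = 5; log2 fold change -6.73 ± 0.77, SE, limma adjusted p = 0.000278). Muscle creatine kinase Ckm fell from 982 ± 417 to 18.6 ± 27.1 RPKM. The other 8 genes with the largest falls were also of muscle. They were the troponins Tnnc2 (log2 fold change -6.47) and Tnnt3 (-6.44), the sarcomere proteins Tcap (-6.44) and Csrp3 (-6.05), the calcium pump Atp2a1 (-6.34), the myosins Myh1 (-6.21) and Myl1 (-6.13), and the calcium buffer Pvalb (-5.98). In the skeletal muscle list 19 of 20 members fell and 0 rose (median log2 fold change -5.67, camera adjusted p = 5.30e-22; adjusted p = 0.307 with an estimated correlation), and all 20 fell when adjusted over the list alone. The giant sarcomere proteins Ttn (-3.55) and Neb (-3.95) and the calcium channel Ryr1 (-4.24) had the smallest p among its members. The adipocyte list had 14 of 15 members fallen and 0 risen, the same counts when adjusted over the list alone (median log2 fold change -3.15, camera adjusted p = 9.89e-11; adjusted p = 0.307 with an estimated correlation). Among them were Car3 (600 ± 329 to 23.7 ± 17.3 RPKM), the lipase Lpl (109 ± 35.2 to 14.9 ± 6.90 RPKM), the lipid droplet coat Plin4 (log2 fold change -3.61) and the insulin-regulated glucose transporter Slc2a4 (-2.74). In the nerve and Schwann cell list 6 of 9 members fell and 0 rose, 7 fallen when adjusted over the list alone (median log2 fold change -1.44, camera adjusted p = 0.000318; adjusted p = 0.311 with an estimated correlation). Among those fallen were the myelin genes Ncmap (log2 fold change -1.19) and Prx (-1.44). The macrophage and dendritic cell list had 7 of 19 members fallen and 0 risen, 9 fallen when adjusted over the list alone (median log2 fold change -1.04, camera adjusted p = 0.00391; adjusted p = 0.479 with an estimated correlation). Genes that fell included lysozyme Lyz2 (-1.84), the complement genes C1qa (-1.68) and C1qc (-1.84) and the scavenger receptor Cd163 (-2.29). The mast cell list had 5 of 10 fallen and 0 risen, 7 fallen when adjusted over the list alone (median log2 fold change -1.26, camera adjusted p = 0.00716; adjusted p = 0.364 with an estimated correlation). The mast cell proteases Mcpt4 (-2.24), Cma1 (-2.27) and Cpa3 (-2.19) fell.

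On the epidermal side, 4 of 41 hyperproliferative and stress genes rose and 1 fell in tumors against Dlx3 KO skin, 12 and 1 when adjusted over the list alone (median log2 fold change 1.41, camera adjusted p = 3.72e-14; adjusted p = 0.307 with an estimated correlation). Wound keratin Krt6a rose from 462 ± 159 RPKM (SD, n = 3) to 3495 ± 1855 RPKM (n = 5; limma adjusted p = 0.00974), and the antimicrobial Defb4 had a log2 fold change of 3.21. The xenobiotic and NRF2 list had 5 of 20 members risen and 1 fallen, 6 and 3 when adjusted over the list alone (median log2 fold change 0.41, camera adjusted p = 0.000246; adjusted p = 0.307 with an estimated correlation). Besides Gsta4, Gsta1 (log2 fold change 3.19) and the aldo-keto reductase Akr1b8 (1.66) rose, while Cyp1b1, a cytochrome P450 that activates DMBA, fell (-2.24). The G2 and M phase list had 3 of 37 members risen and 0 fallen, with all 37 higher and 16 risen when adjusted over the list alone (median log2 fold change 0.75, camera adjusted p = 7.67e-21; adjusted p = 0.307 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex (17.9 ± 5.60 to 42.4 ± 12.3 RPKM), the kinetochore gene Ndc80 (log2 fold change 1.24) and Birc5 (1.19) rose, and the kinase Cdk1 (1.22, adjusted p = 0.0696) did not pass. The ERBB list as a whole did not pass (median log2 fold change -0.03, camera adjusted p = 0.382), and that median was 0.17 and 0.31 with median-ratio and quantile scaling. The ligand amphiregulin, Areg, rose (5.43 ± 1.56 to 21.7 ± 9.58 RPKM, limma adjusted p = 0.0436). Epidermal growth factor Egf (1.40 ± 0.417 to 0.282 ± 0.179 RPKM, adjusted p = 0.0160) and the ERBB4 ligand Nrg4 (3.09 ± 0.764 to 1.01 ± 0.817 RPKM, adjusted p = 0.0408) fell. Adjusted over the list alone, 3 members rose and 3 fell. Egfr (log2 fold change -0.49, adjusted p = 0.289), Erbb2 (-0.46, adjusted p = 0.467), Erbb3 (-0.53, adjusted p = 0.361) and Dlx3 (-0.68, adjusted p = 0.591) did not pass.

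In all, 1075 genes changed between tumors and Dlx3 KO skin in limma, 142 risen and 933 fallen, of which 972 had groups that did not overlap (19.4% of all genes did, against 3.57% by chance). The median gene had a log2 fold change of -0.23, which became 0.02 with median-ratio scaling and 0.09 with quantile normalization. With these the split became 344 risen and 788 fallen, and 487 risen and 634 fallen. Leaving out Dlx3 KO skin 1, 2 or 3 gave 548, 477 and 347 genes, leaving out tumor 2, 3 or 4 gave 550, 559 and 699, and leaving out tumor 1 gave 2867. Of the 8 such fits, only 1, without tumor 1, kept the calls of Areg, Birc5, Ndc80, Nrg4, Cd163 and Cpa3 (adjusted p up to 0.184, Nrg4 without Dlx3 KO skin 3). The calls of C1qa and C1qc were kept in 2, those of Defb4, Lyz2, Cma1 and Prx in 3 and those of Cdc20, Cyp1b1 and Mcpt4 in 4. Gsta1 was kept in 5, Egf in 6 and Krt6a in 7. The first run alone (tumor 5 and Dlx3 KO skins 2 and 3) gave 1627 genes and the second alone (tumors 1 to 4 and Dlx3 KO skin 1) gave 204. Each has an arm of 1 library that is taken to vary like the others. Within runs the medians were -3.54 and -5.88 for skeletal muscle, -3.33 and -2.96 for adipocytes, 0.76 and 1.17 for the G2 and M phase, -0.89 and 2.74 for the hyperproliferative list, and -0.27 and 0.41 for the xenobiotic list. The test for the hyperproliferative and xenobiotic lists pointed upward in the first run although the medians were below 0. The macrophage list had medians of -2.35 and -0.57 and did not pass in the second run (camera adjusted p = 0.136). Libraries with high Xist alone gave 272 genes, the Xist level as an added term gave 504, weighting libraries gave 5969, and leaving out WT skin 1 and tumor 5, the libraries highest in Rn45s, gave 681.

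**Figure D3:**
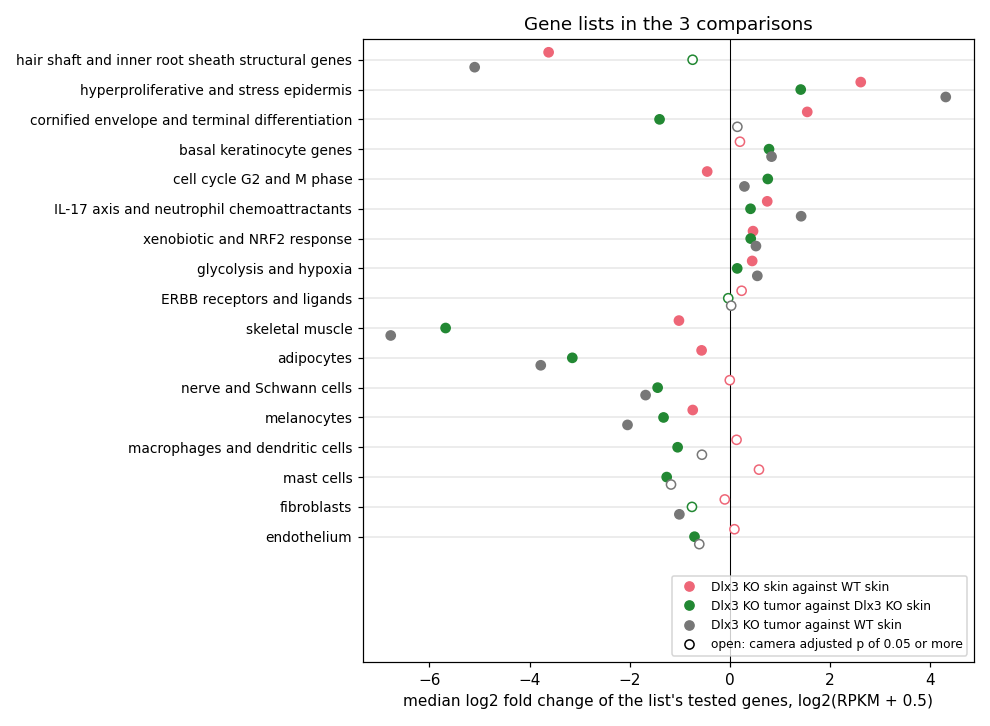
Median log2 fold change of the tested members of 17 gene lists (horizontal axis, log2(RPKM + 0.5) scale) in the 3 comparisons, with filled points where camera with its preset correlation gave an adjusted p under 0.05 and open points elsewhere; with an estimated correlation 0 lists passed. Skeletal muscle lies at -5.67 in tumors against Dlx3 KO skin and -6.77 against WT skin, and hair shaft genes at -3.62 in Dlx3 KO skin against WT skin.

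Tumors (n = 5) were also compared with WT skin (n = 3), the sum of both steps. Most hyperproliferative and stress genes rose (31 of 41), and most hair shaft (57 of 59), skeletal muscle (20 of 20) and melanocyte genes (10 of 12) fell. Smaller parts of the IL-17 list (5 of 20) and the glycolysis list (8 of 26) rose. Krt13 rose from 1.28 ± 1.02 to 380 ± 562 RPKM (SD; log2 fold change 6.82 ± 0.88, SE, limma adjusted p = 0.000426). Likewise Krt6b rose from 60.5 ± 82.6 to 3248 ± 2160 RPKM and Slpi from 5.87 ± 4.16 to 738 ± 753 RPKM. Gsta4 (log2 fold change 5.92), Sprr2a3 (5.94), Sprr3 (5.62), Sprr2i (5.51) and Sprr2k (5.49) were also among the largest rises. Sprr2a1 and Sprr2a2 held identical values in every library (both 5.74), as copies that share reads do, and count as 1 uncertain measurement. Of 41 hyperproliferative and stress genes 31 rose and 1 fell, 35 and 1 when adjusted over the list alone (median log2 fold change 4.31, camera adjusted p = 2.77e-26; adjusted p = 0.276 with an estimated correlation). Krt6a (184 ± 119 to 3495 ± 1855 RPKM) and Sprr2f (log2 fold change 4.96) rose. The IL-17 axis list had 5 of 20 members risen and 0 fallen, 6 and 0 when adjusted over the list alone (median log2 fold change 1.42, camera adjusted p = 2.01e-07; adjusted p = 0.276 with an estimated correlation). The cytokines Il24 (3.22), Il19 (2.83) and Il23a (2.08) and the neutrophil chemokine Cxcl1 (3.19) rose. The glycolysis and hypoxia list had 8 of 26 members risen and 1 fallen, the same counts when adjusted over the list alone (median log2 fold change 0.55, camera adjusted p = 1.80e-06; adjusted p = 0.343 with an estimated correlation). The glucose transporter Slc2a1 (22.1 ± 12.9 to 136 ± 47.6 RPKM), carbonic anhydrase Car12 (13.3 ± 7.56 to 58.1 ± 11.5 RPKM) and phosphofructokinase Pfkl (log2 fold change 1.79) rose, and aldolase Aldoa, also abundant in muscle, fell (-1.51).

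Of 59 hair shaft and inner root sheath genes, 57 fell and 2 rose in tumors against WT skin, the same counts when adjusted over the list alone (median log2 fold change -5.09, camera adjusted p = 2.45e-20; adjusted p = 0.343 with an estimated correlation). The hair keratins Krt83 (452 ± 242 RPKM, SD, n = 3, to 5.91 ± 3.45 RPKM, n = 5; limma adjusted p = 0.000185), Krt81 (log2 fold change -5.91), Krt33b (-5.81) and Krt36 (-4.06) fell. All 20 skeletal muscle genes fell, likewise when adjusted over the list alone (median log2 fold change -6.77, camera adjusted p = 3.20e-21; adjusted p = 0.276 with an estimated correlation). The largest falls were Pvalb (1800 ± 308 to 14.0 ± 24.8 RPKM, log2 fold change -8.32), the fast myosin Myh4 (-8.10), Ckm (-7.64), Tnnc2 (-7.58), Tcap (-7.45), Atp2a1 (-7.17), Myl1 (-7.06), Tnni2 (-6.98), the calcium store protein Casq1 (-6.97) and Tnnt3 (-6.94). The muscle genes Mylpf (-6.42), Ckmt2 (-6.63) and Ryr1 (-5.51) fell too. The melanocyte list had 10 of 12 members fallen and 0 risen, 12 fallen when adjusted over the list alone (median log2 fold change -2.04, camera adjusted p = 1.48e-06; adjusted p = 0.343 with an estimated correlation). Pigment cell genes that fell were Pmel (47.0 ± 21.5 to 3.73 ± 1.92 RPKM), Tyrp1 (-2.69), Slc45a2 (-2.40) and Trpm1 (-2.64). In the ERBB list 3 of 13 members rose and 1 fell, 4 and 1 when adjusted over the list alone (median log2 fold change 0.02, camera adjusted p = 0.0674; adjusted p = 0.458 with an estimated correlation). It passed without tumor 1 (camera adjusted p = 0.0430 at the preset correlation). In the first run alone, where tumor 5 was the only tumor, the median of the ERBB list was -0.55. The EGFR ligands Hbegf (5.04 ± 1.69 to 42.1 ± 27.2 RPKM, adjusted p = 0.00456), Epgn (2.26 ± 0.546 to 13.9 ± 7.94 RPKM, adjusted p = 0.0176) and Areg (5.23 ± 2.16 to 21.7 ± 9.58 RPKM, adjusted p = 0.0216) rose. The ligand Egf fell (1.81 ± 0.730 to 0.282 ± 0.179 RPKM, adjusted p = 0.00302). Egfr (log2 fold change -0.26, adjusted p = 0.583), Erbb2 (-0.04, adjusted p = 0.961) and Erbb3 (0.02, adjusted p = 0.973) did not pass, and each had the other sign in some fits.

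Between tumors and WT skin, 2208 genes changed in limma, 506 risen and 1702 fallen, of which 1741 had groups that did not overlap (16.1% of all genes did, against 3.57% by chance). The median gene had a log2 fold change of -0.14, which became 0.08 with median-ratio scaling and 0.14 with quantile normalization. The split then became 1322 risen and 1533 fallen, and 1461 risen and 1373 fallen. Leaving out WT skin 3 gave 1308 genes and leaving out the library labelled WT skin 2 gave 1831, and with run as an added term 705 genes passed. The calls of Il24, Trpm1, Tyrp1, Slc45a2 and Pfkl were lost with that term. Those of Il23a, Il19, Cxcl1, Epgn and Areg were lost with it and without WT skin 3 (adjusted p = 0.0560, 0.0814, 0.0702, 0.0527 and 0.0669). Of the 8 fits that each left out 1 library, 3 kept the call of Il19, 5 that of Areg (adjusted p = 0.0894 without the library labelled WT skin 2) and 6 that of Epgn (adjusted p = 0.0630 without WT skin 1). The first run alone (tumor 5 and all WT skins) gave 1604 genes, with medians of -3.86 for hair shaft, -4.44 for skeletal muscle, 2.49 for hyperproliferative, 0.83 for IL-17, 0.31 for glycolysis and -2.16 for melanocyte genes. No WT skin was in the second run. Libraries with high Xist alone, where the only WT library is the one labelled WT skin 2, taken to vary like the others, gave 192 genes, with medians of -1.68 for hair shaft and 2.30 for hyperproliferative genes.

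The series set the genes of both steps against each other, Dlx3 KO skin against WT skin and tumor against Dlx3 KO skin. With 0 genes called in the first step, 0 genes were called in both in limma, and 424 had an unadjusted p under 0.05 in both. Of these 52 were higher in both steps (32.7 for independent lists, 0.5 in 20 simulations of unchanged groups that share the Dlx3 KO skins) and 149 lower in both (103 and 0.7). Another 196 were higher and then lower (158 and 90.6), and 27 lower and then higher (21.4 and 92.5). The shared skins enter both steps with opposite sign, so chance alone gives a negative relation. The covariance of the fold changes over 14233 genes was -0.0103 against a simulated -0.0801, a difference of 0.0698; the correlation was -0.02 against -0.56, and 42.7% of genes had the same sign against 31.1%. The 3 shared skins cannot be divided into separate sets of at least 2 libraries, so part of any excess may come from them. The simulation also gave each gene one spread in all groups. Correlations between libraries were 0.965 to 0.980 in the Dlx3 KO skins, 0.887 to 0.952 in WT skin and 0.874 to 0.972 in tumors. The simulated values may therefore be too negative and the excess over them too large. Without the library labelled WT skin 2, 21 genes passed in both steps, 8 risen in both, 10 fallen in both, 2 risen and then fallen and 1 fallen and then risen, and without tumor 5 there were 2.

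The authors' deposited table gives p-values and q-values for the same comparisons. In the authors' deposited table, a total of 7 genes had a q-value under 0.05 between Dlx3 KO skin and WT skin, 561 between tumor and Dlx3 KO skin and 2122 between tumor and WT skin. All 7 of the first set in the authors' deposited table were lower in Dlx3 KO skin and had a mean of at most 0.0487 RPKM over the 11 libraries, below the filter used here. Of the genes called here, 461 and 1544 also had a q-value under 0.05 in the authors' deposited table for the tumor comparisons. The authors' deposited table gives Dlx3 a ratio of 0.197 (p = 0.0509) in Dlx3 KO skin against WT skin, 0.589 in tumor against Dlx3 KO skin and 0.116 in tumor against WT skin.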

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

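The libraries and named genes below were listed because 1 of the 5 tumors lay far from the other 4: its gap to the nearest, divided by the range of the group, was above 0.71, which chance exceeds in about 1 of 20 groups. This held for 13 of 112 named genes (5.6 expected) and 4 of 8 library measures (0.4 expected). Genes of the same tissue move together, so flags in the same tumor are not separate observations, and the excess was not tested. Tumor 5 was highest in the muscle genes Pvalb (0.720), Ttn (0.764), Ryr1 (0.720), Neb (0.811), Myh4 (0.721), Ckmt2 (0.794) and Mylpf (0.735) and lowest in the envelope gene Sprr2g (0.852) and the EGFR ligand Ereg (0.752). Its median over skeletal muscle genes was 19.5 RPKM, against 3.53 RPKM in the next tumor (0.854), and its Rn45s was 11833 RPKM against 3242 (0.806). Tumor 5 was the only tumor of the first run, so among the tumors its values cannot be told apart from an effect of run. Tumor 3 was highest in Gsta1 (0.762). Tumor 1 was highest in the sodium channel Scn7a of Schwann cells (0.807), the macrophage receptor Cd163 (0.751) and the adipocyte median (12.7 against 4.78 RPKM, 0.723). It was lowest on the first principal component (0.804) and in amphiregulin, Areg, with 6.08 RPKM against 22.9 to 32.4 in the others (0.790).

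That tumor 1 lay between the Dlx3 KO skins and the other tumors was weighed against 2 technical explanations, and the test of sequencing run was chosen only after the result was seen. Whole skin mixed into the piece would keep one fraction of the skin level for all cell types. The fraction kept was -0.01 for skeletal muscle (n = 19 genes), 0.17 for adipocytes, 0.13 for melanocytes, 0.36 for mast cells, 0.74 for macrophages and 0.83 for fibroblasts. Among lists with at least 5 such genes it was highest for sebaceous genes (n = 10), with a range over cell types of 1.01 (permutation p = 3e-05). That p compared only the lowest and highest of 9 lists, picked for this from the same values. It also took genes of 1 library as independent, so it overstates the certainty. The fractions argue against one fraction of whole skin for all cell types. They do not bear on admixed skin without the layers under the dermis. On the first principal component, tumor 1 lay 46.8 from the nearest of the other 3 tumors of its run, which span 11.4, so run does not account for its place. No biological explanation was tested.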

How the results depend on the processing

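In the settings in which single genes were followed, directions of named genes held except for Egfr, Erbb2 and Erbb3, while numbers of called genes depended on single libraries; the alternatives on Xist, single runs, Rn45s and unadjusted p were chosen only after the data were seen, and the cause of each move below was not tested unless given. Of the 50 named genes called in tumor against Dlx3 KO skin, 27 stayed called in all 17 settings in which single genes were followed and 23 were lost in some. Single genes were not followed in the block fit and in limma without trend and robust. Of 46 called in tumor against WT skin, 35 stayed and 11 were lost in some. Of 36 not called in Dlx3 KO skin against WT skin, 17 passed in some of 15 settings, with 229 genes called without the library labelled WT skin 2. Called lists with an estimated correlation were 0, 0 and 0, and with fry 0, 4 and 13, in Dlx3 KO skin against WT skin, tumor against Dlx3 KO skin and tumor against WT skin. A threshold of 0.01 left 387 and 921 genes in the tumor comparisons by construction. Library weights gave 2 genes in Dlx3 KO skin against WT skin and 5969 in tumor against Dlx3 KO skin, and run as a term gave 705 in tumor against WT skin. The Xist level as a term gave 504 genes in tumor against Dlx3 KO skin. With fewer libraries and an arm of 1 library in some, taken to vary like the others, high Xist alone gave 4, 272 and 192 genes (and 5 lists in the first), the first run alone 1627 and the second 204 in tumor against Dlx3 KO skin, and leaving out both libraries high in Rn45s 681. At unadjusted p, 424 genes overlapped between the steps.

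Leaving out each library gave 0 to 229 genes in Dlx3 KO skin against WT skin, 347 to 2867 in tumor against Dlx3 KO skin and 1308 to 3284 in tumor against WT skin, and 0 to 21 genes in both steps. Dlx3 in Dlx3 KO skin against WT skin ranged from -3.32 (without the library labelled WT skin 2, where it passed) to -1.56 (without WT skin 3). Erbb receptors, never called, changed sign in some fits. Egfr in Dlx3 KO skin against WT skin ranged from -0.00153 to 0.55 over left-out libraries. In tumor against WT skin, Egfr ranged from -0.492 to 0.0543 (quantile 0.0212), Erbb2 from -0.45 to 0.21 (median-ratio 0.21, quantile 0.10, library weights 0.0635) and Erbb3 from -0.41 to 0.26 (run as a term -0.46).

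A block by replicate number, in fits of the 2 compared groups alone, gave 13, 224 and 752 genes and 2 in both steps. The labels do not say that equal numbers share anything, and correlations of same-numbered libraries were -0.230, -0.132 and 0.168 for Dlx3 KO skin and WT skin, 0.00853, -0.00296 and -0.108 for tumor and Dlx3 KO skin, and -0.406, -0.0833 and 0.185 for tumor and WT skin, so numbers were not taken as pairs. Depth was lowest in the library labelled WT skin 2 (29265111 alignments) and highest in Dlx3 KO skin 1 (75707445).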

Other observations

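Further gene lists moved with the groups in camera at its preset correlation, with 0 lists passing at an estimated correlation (smallest adjusted p = 0.573, 0.307 and 0.276 in the 3 comparisons). In Dlx3 KO skin against WT skin (n = 3 each), AP-1 factors (median log2 fold change 0.64, camera adjusted p = 0.00510, all 10 higher), epithelial junctions (0.43, adjusted p = 0.00420), glycolysis genes (0.44, adjusted p = 4.41e-05), T cell genes (0.71, adjusted p = 0.00169) and sebaceous genes (0.78, adjusted p = 0.00725) were higher. Skeletal muscle (-1.02, adjusted p = 5.42e-05), adipocyte (-0.57, adjusted p = 0.00627), melanocyte (-0.74, adjusted p = 9.37e-05), erythrocyte (-2.36, adjusted p = 0.00456), S phase (-0.29, adjusted p = 1.64e-05) and hair follicle regulator genes (-0.34, adjusted p = 0.00113) were lower, with the library labelled WT skin 2 counted among the WT skins. In tumors (n = 5) against Dlx3 KO skin (n = 3), basal keratinocyte (0.78, adjusted p = 2.20e-06), S phase (0.51, adjusted p = 1.58e-16), IL-17 (0.41, adjusted p = 0.00123) and matrix protease genes (0.33, adjusted p = 1.33e-05) were higher, and cornified envelope (-1.41, adjusted p = 0.00533, 5 of 44 fallen), sebaceous (-1.16, adjusted p = 0.00583), endothelial (-0.71, adjusted p = 0.00533) and melanocyte genes (-1.33, adjusted p = 0.000795) were lower. Hair shaft genes did not pass there (-0.75, adjusted p = 0.750). The p53 target list passed upward (adjusted p = 0.00528) with a mean of 0.05 and a median of -0.05. In tumors against WT skin, adipocyte (-3.78, adjusted p = 5.04e-11) and nerve genes (-1.68, adjusted p = 0.00110) were lower, basal keratinocyte genes (0.83, adjusted p = 1.88e-05) were higher, and cornified envelope genes did not pass (median 0.15, mean -0.26, adjusted p = 0.133).

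Other ways to divide the libraries were counted for each comparison. In Dlx3 KO skin against WT skin, the real split called 0 genes, so all 10 of 10 splits gave as many by construction (highest other 0) and the number of genes tests nothing. For lists, 2 of 10 splits gave as many (20, highest other 20), too few splits to tell the real one from chance. In tumor against Dlx3 KO skin, 2 of 56 splits gave as many genes (1075). The highest other, 2232, set tumors 2, 3 and 5 against the rest, and 8 of 56 gave as many lists (25, highest other 29). In tumor against WT skin, 1 of 56 splits, the real one, gave as many genes (2208, highest other 1449), and 11 of 56 as many lists (22, highest other 27). Chance is therefore not excluded for the numbers of lists.

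The library labelled WT skin 2 resembled the Dlx3 KO skins in Dlx3 and hair shaft genes, and the test of a swap was chosen only after the result was seen. Dlx3 is itself a factor of the hair follicle, so low Dlx3 and low hair shaft genes may not be independent signs of its genotype. Over all tested genes its correlation was 0.928, 0.949 and 0.947 with Dlx3 KO skins 1, 2 and 3. With WT skin 1 and 3 it was 0.894 and 0.887. A swap would leave a WT library among those labelled Dlx3 KO skin, and the highest of these had 8.88 RPKM of Dlx3 against 49.9 in WT skin 1. No partner out of place was thus seen, which argues against a swap only as far as WT skin 1 and 3 give the WT level of Dlx3. For a Dlx3 KO skin wrongly labelled, the median position of this library was taken over 229 genes, with 0 at the Dlx3 KO skins and 1 at WT skin 1 and 3. It was 0.194. Dlx3 KO skins 1, 2 and 3, each left out in turn, lay at -0.112, 0.138 and 0.0209. Each of these was placed on its own 144, 175 or 173 called genes, with 0 at the mean of the remaining Dlx3 KO skins. The library labelled WT skin 2 lay at 0.279 (upper quartile 0.468) over the 63 genes higher in Dlx3 KO skin. Over the 166 lower genes it lay at 0.184 (upper quartile 0.251). The left-out Dlx3 KO skins were not placed by direction, and the upper quartile of Dlx3 KO skin 2 was 0.284. The positions therefore do not decide it. Some named genes, picked after their values were seen, lay on the WT side in that library, such as Fgfbp1 (42.6 RPKM, Dlx3 KO skins 109 to 139) and Ereg (1.75 RPKM, Dlx3 KO skins 5.95 to 15.1). These genes were named from a fit that counts this library as WT. That choice favors genes where it lies on the WT side. Without this library Fgfbp1 also passed (limma adjusted p = 0.000257) and Ereg did not (adjusted p = 0.123). Both were picked after their values were seen, so they do not decide its label. Sex could also set WT skin 2 apart, since WT skin 1 and 3 have low Xist. Of the 229 genes, 37.6% differed with the same sign between low-Xist and high-Xist tumors, against 16.2% to 84.3% in other splits of the tumors (10 splits), which does not decide it either.

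Muscle and fat transcripts fell in tumors against Dlx3 KO skin, and the tests of cell shares and tissue layers were chosen only after the result was seen. RPKM scaling is excluded for muscle, with a muscle median of -5.39 after median-ratio rescaling against -5.67. For muscle, the medians argue against one lower share of all cells other than keratinocytes. The muscle median minus that of fibroblasts (-0.76) was -4.92 and minus that of endothelium (-0.71) was -4.97 (permutation p = 1e-05, the smallest that 100000 resamples give, for each). That p took the genes of a list as independent, while the muscle list had an estimated correlation of 0.71, so it overstates the certainty. Adipocyte genes were not tested in this way. Whether tissue layers under the dermis were left out of the tumor pieces stays open. The share of members with a log2 fold change below -1 (20 of 20 muscle and 14 of 15 adipocyte genes, 93.3%) restates the pattern and does not test this.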
